A study of Homo sapiens with 22 samples.

How the data were processed

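Small RNA from H1 human embryonic stem cells with Flag-tagged AGO2 was sequenced after immunoprecipitation with the M1 anti-Flag antibody (2 samples) or with rabbit IgG (2 samples). Groups and replicate numbers come from the sample titles. The labels describe the crosslinking and RNA immunoprecipitation experiments of the series, and the small RNA library preparation is not given in the sources used here. The remaining 18 samples were not analysed here. The AGO2 values are RPM, reads per 1000000, per the file headers, and the IgG values are raw read counts, per the file headers. Both are given per mature miRNA, with 2578 names in every file. The submitters' processing notes name the build hg19, CASAVA 1.8.2 and Bowtie, without saying which step used them. The miRNA annotation version, the mismatches allowed and the treatment of reads that match several miRNAs are not given in the sources used here.

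Each deposited RPM column summed to 1000000 over the listed miRNAs, so its denominator is the reads counted on miRNAs. All RPM values (100%) were whole multiples of the smallest value above 0 within 1e-06 reads, which recovered 1121722 and 1130345 reads for the AGO2 libraries. The IgG counts were divided by their totals of 9024 and 4628 to give RPM in the same way. RPM and shares compare the makeup of libraries and remove any difference in how much RNA each pulldown brought down. Names were matched to symbols of a RefSeq gene table on another assembly, GRCh38.p14, for 2544 of 2578 names; its coordinates were not used. In that table the miR-302a to miR-302d and miR-367 genes neighbour each other, as do the genes from miR-17 to miR-92a-1.

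The test planned before the data were examined was edgeR's quasi-likelihood test on counts, with limma on log2(value + 1) in its place should the values be RPM. Because the AGO2 values are RPM, limma with a mean-variance trend was used, on miRNAs with at least 1 RPM in at least 2 libraries, with Benjamini-Hochberg adjustment at 0.05 and no replicate block. Fold changes are on the log2(RPM + 1) scale, which understates changes of low miRNAs. This scale also gives a miRNA with 0 reads in a shallow library a value of 0 even where the depth could not have shown it. edgeR with TMM factors on recovered reads was added after the RPM values were seen, and DESeq2 was run on the same reads. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

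Shares are percentages of all miRNA reads of a library, computed from the deposited values, and are given as mean ± SD of 2 libraries. The ratio of IgG to AGO2 shares uses reads pooled over both libraries of each group, with an exact conditional binomial 95% interval. These ratios were chosen after the depths were seen and their intervals are not adjusted for the number of miRNAs or lists. All intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Nothing says that the replicates come from separate cultures, so p-values measure only the spread between these samples, which may be technical. A miRNA at 0 in both IgG libraries was compared with a floor of 3 reads over both, 220 RPM. For such a miRNA no fold is given where its AGO2 value is at or under the floor too. Folds and ratios of miRNAs with IgG reads are given even where both groups lie under it.

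The 15 lists were fixed before the data were examined: the miR-302 and miR-371 clusters (with miR-367, miR-372 and miR-373), the miR-17 cluster and its paralogs, the chromosome 19 and chromosome 14 clusters, the miR-200 and let-7 families, markers of neural, mesenchymal, endoderm, blood and muscle cells, mirtrons and other Microprocessor-independent miRNAs, broadly conserved families, entries overlapping other RNA classes or repeats, and names with a number of 1000 or above. Lists were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists, and also with an estimated correlation and with fry. Arm usage was tested with limma on log2((5p + 0.5) / (3p + 0.5)) for hairpin names with at least 10 reads in each library. Thinning used 100 random draws.

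miRNAs were named by a rule fixed in advance. It took the 12 with the largest mean AGO2 share, the 8 largest and 8 smallest fold changes among called miRNAs with a mean of at least 50 RPM in the higher group and no overlap between groups, and the 3 most abundant tested members of each list. For arms it took the 5 hairpins with the most reads and up to 5 called hairpins with the smallest p. Other miRNAs named in the text were chosen after their values were seen.

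The code was tested on simulated data with 200 miRNAs changed, at equal and at the real depth. At equal depth limma recovered 79.8% of 4-fold changes and called 1 of 381 unchanged miRNAs higher, and edgeR recovered 100% and called 3 of 205 higher. At the real, unequal depth limma recovered 50.8% and called 176 of 315 unchanged miRNAs higher, while edgeR recovered 24.5% and called 4 of 168 higher. Each percentage is of the changed miRNAs that passed that test's own filter, here 183 for limma and 98 for edgeR, so the 2 are not comparable. Of the 17 changed miRNAs with at least 5 expected IgG reads at their AGO2 share, limma recovered 58.8% and edgeR 76.5%. For 16-fold changes at the real depth limma recovered 78.8% with 174 of 318 unchanged called higher, and edgeR 64.3% with 20 of 172. Lists and hairpins were simulated at equal depth only. There the 1 list changed 4-fold was called, with no other of the 15, and of 232 hairpins 9 of 10 changed 8-fold were called with 0 unchanged ones; these figures say nothing of the real depth, where 22 hairpins could be tested. As a further check, IgG libraries were drawn 100 times at their own totals from the pooled AGO2 composition and the tests rerun. With no change in composition, limma then called a median of 11 hairpins and camera a median of 4 lists.

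Alternatives planned before the data were examined were scaling by total counts, RLE or upper quartile factors, no scaling for depth, DESeq2, other count filters, a replicate block, a test against a 2-fold change, exclusion of overlapping entries, and leaving out each library. Alternatives chosen after seeing the data were edgeR with TMM factors, TMM scaling in limma, pseudocounts of 0.1, 10 and 100 RPM, a minimum mean of 1000 RPM, limma without the trend and thinning all libraries to the smallest total.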

Results

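The series examined where the Microprocessor, the nuclear Drosha and DGCR8 complex that cuts primary miRNA transcripts, binds RNA in human embryonic stem cells. It also sequenced small RNA bound to AGO2, the Argonaute protein that carries mature miRNAs to their targets. H1, an established human embryonic stem cell line, carried a Flag tag at the start of AGO2. AGO2 was pulled down with an anti-Flag antibody in 2 samples, and 2 control samples were pulled down with rabbit IgG. Those 4 of the 22 samples are described here, and the other 18 (crosslinking and RNA immunoprecipitation of DGCR8, Drosha and a control) were not analysed here. Each of the 4 libraries listed the same 2578 mature miRNAs. The AGO2 libraries held 1121722 and 1130345 miRNA reads in replicates 1 and 2, and the IgG libraries 9024 and 4628. An AGO2 library therefore held between 124 and 244 times as many miRNA reads as an IgG library. A single read was worth 0.891 and 0.885 RPM (reads per 1000000 miRNA reads) in the AGO2 libraries, and 111 and 216 RPM in the IgG libraries. No label gives the input or the number of reads sequenced, so these totals are not a measured yield.

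The first question was which miRNAs were most abundant after AGO2 pulldown. The miR-302 cluster, which includes miR-367 and is the characteristic miRNA cluster of human pluripotent cells, supplied their 5 most abundant miRNAs. Of all miRNA reads, miR-302b-3p took 29.2% ± 0.18 (SD, n = 2), miR-302a-3p 16.9% ± 0.21, miR-302d-3p 13.8% ± 0.42, miR-367-3p 13.7% ± 0.64 and miR-302c-3p 6.42% ± 0.014. Together these 5 held 79.8% of the reads of AGO2 replicate 1 and 80.0% of those of replicate 2. The next places belonged to miR-92a-3p (2.08% ± 0.012), miR-19b-3p (1.26% ± 0.073), miR-20a-5p (1.17% ± 0.0082), miR-17-5p (1.10% ± 0.0078) and miR-18a-5p (0.872% ± 0.11), all of the proliferation-associated miR-17 cluster. Then came miR-21-5p (0.719% ± 0.047) and miR-130a-3p (0.612% ± 0.0018).

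The IgG libraries held the same leading miRNAs at nearly the same shares. In them miR-302b-3p took 29.4% ± 0.64 (SD, n = 2), miR-302a-3p 17.0% ± 0.90, miR-302d-3p 15.3% ± 1.35, miR-367-3p 12.5% ± 0.18 and miR-302c-3p 6.27% ± 0.53. The 5 together held 80.8% of the reads of IgG replicate 1 and 80.1% of those of replicate 2. miR-92a-3p held 1.95% ± 0.012, miR-19b-3p 1.35% ± 0.053, miR-20a-5p 0.970% ± 0.21, miR-17-5p 0.904% ± 0.12, miR-18a-5p 0.791% ± 0.32, miR-21-5p 0.603% ± 0.15 and miR-130a-3p 0.450% ± 0.12. Members of the miR-302 family, and of the miR-17 and miR-520 families named later, have near-identical sequences, and the authors' rule for reads that match several of them is not given in the sources used here.

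**Figure D1:**
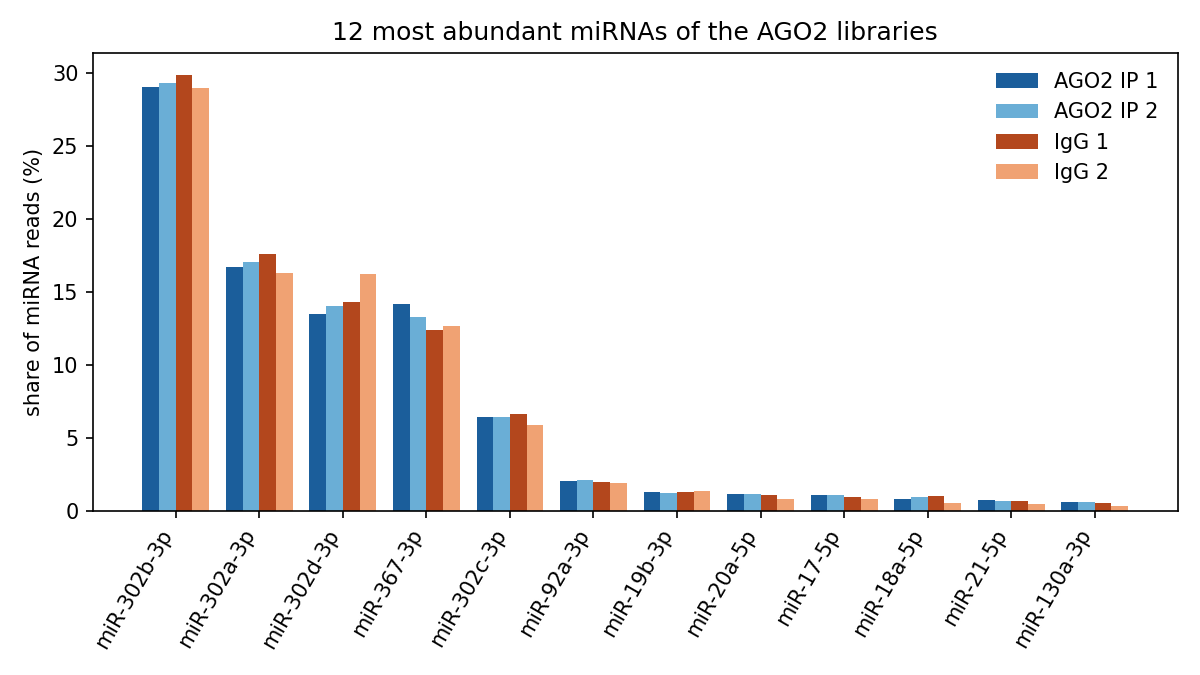
Share of all miRNA reads (percent, vertical axis) of the 12 most abundant miRNAs of the AGO2 libraries, with 1 bar for each of the 4 libraries. The 5 tallest miRNAs belong to the miR-302 cluster and together take 79.8% and 80.0% of the AGO2 reads and 80.8% and 80.1% of the IgG reads.

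Shares of single miRNAs were compared by the ratio of the pooled IgG share to the pooled AGO2 share, with an exact 95% interval. miR-302d-3p had a ratio of 1.09 (1.04 to 1.14), but its ratio lay below 1 with 4 of 6 other scalings, the lowest being 0.811. All 6 lower every ratio, by factors of 0.746 to 0.923, so they can move a ratio below 1 but not above it. miR-367-3p had a ratio of 0.911 (0.869 to 0.956). miR-302b-3p (1.01, 0.982 to 1.04), miR-302a-3p (1.02, 0.977 to 1.06), miR-302c-3p (0.996, 0.931 to 1.06) and miR-92a-3p (0.939, 0.829 to 1.06) had intervals that held 1. Of 81 miRNAs with at least 5 expected IgG reads, 69 had 1 inside the interval, 5 lay above it and 7 below, where chance gives 4.05. Above 1 with miR-302d-3p were miR-378a-3p (2.16, 1.21 to 3.58), miR-151a-5p (2.09, 1.04 to 3.75), miR-27a-3p (1.96, 1.09 to 3.24) and miR-3529-3p (1.70, 1.07 to 2.55). Below 1 with miR-367-3p were miR-361-5p (0, 0 to 0.715), miR-193b-3p (0.384, 0.125 to 0.898), miR-130b-3p (0.425, 0.156 to 0.926), miR-374a-5p (0.490, 0.224 to 0.932), miR-302c-5p (0.588, 0.336 to 0.955) and miR-130a-3p (0.778, 0.600 to 0.992). These miRNAs were picked by their intervals after the values were seen. Of the 12, 0 had an interval clear of 1 against IgG replicate 1 and against IgG replicate 2 when each was used alone: miR-302d-3p had 1.04 (0.984 to 1.10) against the first and 1.18 (1.10 to 1.27) against the second. In the same order miR-3529-3p had 1.00 (0.459 to 1.91) and 3.05 (1.66 to 5.12), miR-374a-5p 0.660 (0.284 to 1.30) and 0.161 (0.0041 to 0.896), and miR-193b-3p 0.465 (0.127 to 1.19) and 0.227 (0.0057 to 1.26).

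**Figure D2:**
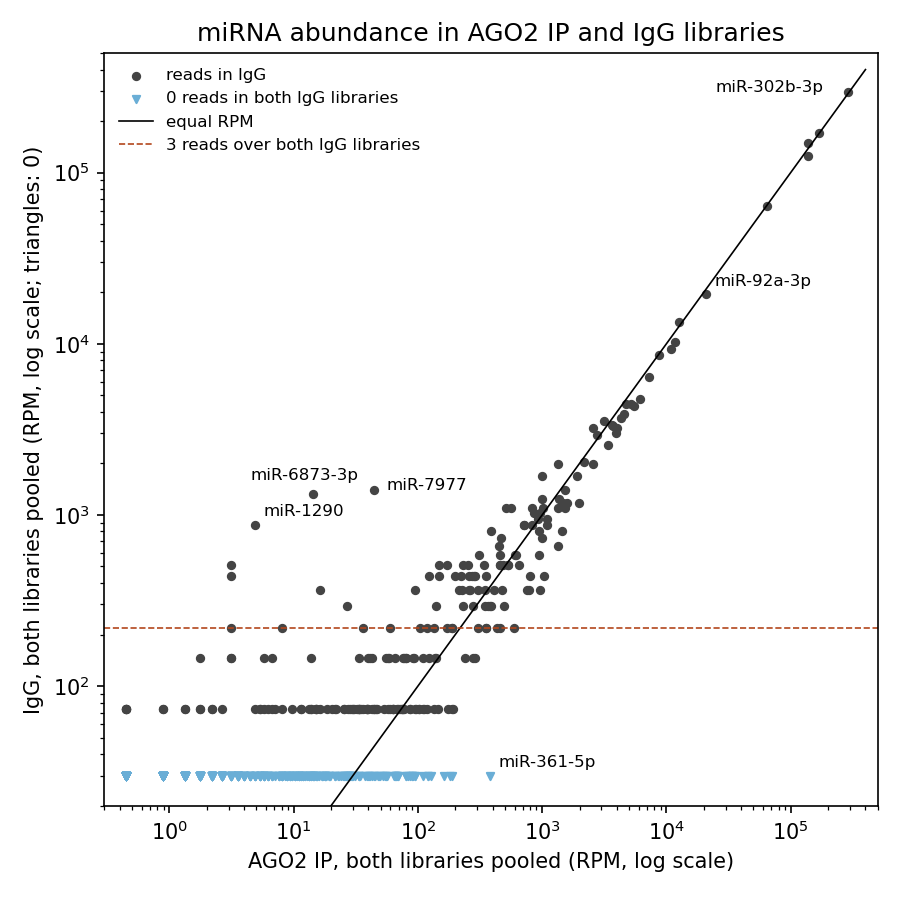
Abundance of each miRNA with AGO2 reads, pooled over the AGO2 libraries (RPM, log horizontal axis) and over the IgG libraries (RPM, log vertical axis), where triangles mark miRNAs with 0 IgG reads, drawn at a fixed height. miR-302b-3p and miR-92a-3p lie by the line of equal RPM, miR-6873-3p, miR-7977 and miR-1290 lie above it, and the dashed line marks 220 RPM, the value of 3 reads over both IgG libraries.

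The test over all miRNAs asked which miRNAs were enriched with AGO2 over the IgG background. limma on log2(RPM + 1) tested 496 miRNAs and, at a Benjamini-Hochberg adjusted p under 0.05, called 258 higher and 13 lower with AGO2. Of the 258, 253 had 0 IgG reads, and 236 would have had under 1 read in both IgG libraries together at their AGO2 share. Only 1 of the 253, miR-361-5p, lay above the value of 3 reads over both IgG libraries: 379 RPM ± 19.0 with AGO2 (SD, n = 2) against 0 reads in IgG (limma adjusted p = 0.00065). No fold is given for it, since its interval held 1 against IgG replicate 1 (0 to 1.08) and against IgG replicate 2 (0 to 2.11) when each was used alone. The other 7 of the 8 largest fitted changes were miR-744-5p, miR-200b-3p, miR-935, miR-187-3p, miR-519d-5p, miR-498 and miR-222-3p, with 110 to 189 RPM in AGO2 and 0 reads in IgG. For these no fold is given either, since both groups lay under the value of 3 reads. The 5 called higher that did have IgG reads were miR-130b-3p (log2 fold change 1.24, SE 0.15, adjusted p = 0.012), miR-302c-5p (0.73, SE 0.14, 0.031), miR-26a-5p (0.40, SE 0.071, 0.028), miR-93-5p (0.37, SE 0.068, 0.029) and miR-92a-3p (0.093, SE 0.016, 0.024). In each of these, both AGO2 libraries lay above both IgG libraries. All 5 calls were lost without AGO2 replicate 1 or without AGO2 replicate 2 (each adjusted p = 0.998) and with upper quartile scaling (adjusted p from 0.114 to 0.677). That of miR-92a-3p was kept under only 4 of 24 other settings, and was also lost without IgG replicate 1 (limma adjusted p = 0.076) and without IgG replicate 2 (0.091).

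The 13 miRNAs called lower with AGO2 rested on few IgG reads, 8 of them on under 10. The most abundant of the 8 smallest fitted changes were miR-7977, with 44.0 RPM ± 13.4 in AGO2 (SD, n = 2) and 1632 RPM ± 1054 in IgG, and miR-6873-3p, with 14.2 ± 3.69 and 1208 ± 486. The share of miR-7977 was 31.7 times as high in IgG (18.3 to 52.1, 19 IgG reads), and that of miR-6873-3p 92.8 times (49.0 to 170, 18 IgG reads). The next ratios were 141 for miR-6743-5p (39.3 to 491), 82.5 for miR-6880-5p (7.46 to 576), 70.7 for miR-499a-5p (11.8 to 310), 47.1 for miR-1260a (4.78 to 248), 27.5 for miR-3960 (5.19 to 94.2) and 25.4 for let-7g-5p (2.78 to 112). Each of these 6 had between 2 and 6 IgG reads. In all 8 both IgG libraries lay above both AGO2 libraries, but the naming rule required this, so it is no separate evidence. Against IgG replicates 1 and 2 alone the ratios were 20.2 and 54.1 for miR-7977, 109 and 60.8 for miR-6873-3p, 71.3 and 278 for miR-6743-5p, 35.7 and 139 for miR-499a-5p, and 13.9 and 54.1 for miR-3960. The interval held 1 against IgG replicate 1 alone for miR-499a-5p (0.791 to 278), miR-3960 (0.333 to 87.8), miR-1260a (0.791 to 278) and let-7g-5p (0.452 to 128), and for let-7g-5p against IgG replicate 2 alone as well (0.881 to 249). Without AGO2 replicate 1, or without AGO2 replicate 2, only miR-6873-3p and miR-7977 were still called lower. The rest of the 13 were miR-4454, miR-9-3p, miR-27a-3p, miR-29b-3p and miR-378a-3p. The last 3 of these had log2 fold changes of -1.02 (SE 0.23, limma adjusted p = 0.046), -0.58 (SE 0.13, 0.042) and -1.16 (SE 0.22, 0.030).

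These counts depended on the test and on single libraries. edgeR on recovered reads called 0 higher, with 22 higher at an unadjusted p under 0.05, and 4 lower: miR-6873-3p (adjusted p = 4.8e-16), miR-1290 (1.3e-13), miR-7977 (2.1e-12) and miR-214-3p (0.0099). Of these, miR-1290 had 1 read in IgG replicate 1 and 11 in IgG replicate 2, and miR-214-3p had 0 and 5. Their ratios of IgG to AGO2 shares against IgG replicate 1 alone were 22.7 (0.527 to 156) and 0 (0 to 26.2), so both calls rested on IgG replicate 2. DESeq2 called 1 higher, miR-367-3p (log2 fold change 0.28, adjusted p = 0.00054), and 13 lower, among them miR-6873-3p, miR-7977 and miR-1290. limma without AGO2 replicate 1, or without AGO2 replicate 2, could test only 231 miRNAs, none of them with 0 IgG reads. It could therefore not test the 253 higher calls with 0 IgG reads, and their loss does not show that they rest on 1 AGO2 library. Without IgG replicate 1 it called 353 higher and 96 lower, and without IgG replicate 2 it called 320 and 89. With IgG libraries drawn from the pooled AGO2 composition at their own depth, limma called 270 higher (median of 100 draws, range 253 to 289) and 6 lower (1 to 14), and edgeR called 0 lower in all of them. Among the 43 miRNAs with a mean of at least 1000 RPM, limma called 0 higher and 0 lower, with 5 at an unadjusted p under 0.05.

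Lists of miRNAs fixed before the data were examined gave the pluripotency-associated groups first. Of all 496 tested miRNAs 258 were called higher, 253 of them with 0 IgG reads. The higher counts in each list therefore mostly count members without IgG reads and do not by themselves show enrichment with AGO2. The miR-302 cluster with miR-367 and the stem cell cluster of miR-371, miR-372 and miR-373, here the miR-302 and miR-371 clusters, held 81.0% ± 0.13 of AGO2 reads and 81.4% ± 0.52 of IgG reads (SD, n = 2). Their ratio of pooled shares was 1.01 (0.988 to 1.03), and 0.751 to 0.929, below 1, with all 6 other scalings. Of 16 tested members, 3 were called higher by limma (miR-302c-5p, and miR-373-5p and miR-372-5p with 0 IgG reads), 0 lower, and 13 did not pass; adjusted over the list alone, 2 were higher and 0 lower. The miR-17 cluster and its paralogs held 9.07% ± 0.052 and 8.31% ± 0.44, a ratio of 0.927 (0.874 to 0.983), which came to 0.951 (0.885 to 1.02) against IgG replicate 1 alone and 0.882 (0.794 to 0.976) against IgG replicate 2 alone. Of its 25 members, 8 were higher, among them miR-93-5p and miR-92a-3p, both lost without AGO2 replicate 1 or 2, 0 were lower and 17 did not pass, and adjusted over the list alone the counts were 8 and 0. The chromosome 19 cluster, primate-specific and known from placenta and stem cells, held 0.902% ± 0.0086 and 0.766% ± 0.017 (ratio 0.845, 0.690 to 1.02). Of its 43 members 18 were higher, all with 0 IgG reads, 0 lower and 25 did not pass, and 18 and 0 adjusted over the list alone; its most abundant members, miR-520c-3p (1091 and 1089 RPM in AGO2 and IgG), miR-520g-3p (967 and 1091) and miR-512-5p (790 and 330), did not pass. The epithelial miR-200 family held 0.371% ± 0.0011 and 0.404% ± 0.070 (ratio 1.05, 0.783 to 1.37, and below 1 with all 6 scalings), with 3 of 7 members higher, 0 lower, 4 not passed, and 3 and 0 adjusted over the list alone. Broadly conserved families held 97.3% ± 0.028 and 96.4% ± 0.93 (ratio 0.993, 0.976 to 1.01), with 88 of 203 members higher, 5 lower and 110 not passed, and 87 and 3 adjusted over the list alone. Tested members with 0 IgG reads numbered 6 in the miR-17 list, 3 in the miR-200 family and 87 in the conserved families.

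miRNAs known from differentiated cells were a small part of both kinds of library. Tested members with 0 IgG reads numbered 5 mesenchymal, 3 neural, 4 let-7, 2 endoderm, 4 blood, 6 chromosome 14 and 3 muscle. Mesenchymal and fibroblast markers, led by miR-21-5p, miR-22-3p and miR-29b-3p, held 1.16% ± 0.060 of AGO2 reads and 1.16% ± 0.083 of IgG reads (SD, n = 2). Their ratio was 1.02 (0.866 to 1.19), and below 1 with all 6 scalings. Of 12 members 5 were higher, 1 lower (miR-29b-3p, whose own ratio had an interval that held 1) and 6 not passed. Adjusted over the list alone the counts were 5 and 1. Neural markers held 0.120% ± 0.00046 and 0.192% ± 0.027, a ratio of 1.65 (1.08 to 2.40) from 27 IgG reads, and 1.44 (0.620 to 2.84) against IgG replicate 2 alone. Of 10 members 3 were higher, 1 lower (miR-9-3p, whose own ratio had an interval that held 1) and 6 not passed. Adjusted over the list alone the counts were 3 and 1. miR-128-3p (337 RPM in AGO2, 546 in IgG), miR-124-3p (222 and 438) and miR-125b-5p (148 and 440) did not pass. The let-7 family, which builds up on differentiation, held 0.0284% ± 0.00016 and 0.0762% ± 0.045, a ratio of 2.32 (1.06 to 4.44) from 9 IgG reads, 1.56 (0.424 to 4.02) against IgG replicate 1 alone and 3.81 (1.23 to 8.93) against IgG replicate 2 alone. Of 7 members 4 were higher, 1 lower (let-7g-5p) and 2 not passed, among them let-7a-5p (214 RPM in AGO2 and 382 in IgG) and let-7d-5p (6.65 and 216), with 4 and 1 adjusted over the list alone. Endoderm and liver markers, led by miR-375, had a ratio of 0.974 (0.518 to 1.67), with 2 of 4 members higher and 0 lower. Blood markers had a ratio of 0.899 (0.108 to 3.27), with 4 of 6 members higher and 0 lower, and the chromosome 14 imprinted cluster a ratio of 1.47 (0.0370 to 8.38), with 5 of 7 higher and 0 lower. Blood markers had 2 IgG reads, both in IgG replicate 1 (ratio 1.36, 0.164 to 4.95, against it alone), and the chromosome 14 cluster 1, in IgG replicate 2 (4.34, 0.109 to 24.7). Adjusted over the list alone, these 3 lists had 2, 4 and 6 members higher and 0 lower. Muscle markers had a ratio of 7.50 (1.51 to 22.9), resting on 3 IgG reads of miR-499a-5p, 3.78 (0.0943 to 21.8) against IgG replicate 1 alone and 14.7 (1.75 to 55.4) against IgG replicate 2 alone, with 3 of 4 members higher, 1 lower and 0 not passed, and 3 and 1 adjusted over the list alone.

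The last groups concerned how a miRNA is made or annotated. Mirtrons and other miRNAs made without the Microprocessor, led by miR-484 and miR-320a, held 0.129% ± 0.00062 of AGO2 reads and 0.0715% ± 0.040 of IgG reads (SD, n = 2), a ratio of 0.627 (0.313 to 1.12). It was 0.776 (0.354 to 1.47) against IgG replicate 1 alone and 0.336 (0.0407 to 1.22) against IgG replicate 2 alone, from 9 and 2 IgG reads. Of 4 members 2 were higher, both arms of miR-877 with 0 IgG reads, 0 were lower and 2 did not pass, with 2 and 0 adjusted over the list alone. miR-484 (801 RPM in AGO2, 385 in IgG) and miR-320a (472 and 330) did not pass. miRNAs whose number is 1000 or above held 0.301% ± 0.0063 and 1.34% ± 0.95, a ratio of 3.72 (3.15 to 4.36). It was 2.21 (1.68 to 2.84) against IgG replicate 1 alone and 6.67 (5.37 to 8.18) against IgG replicate 2 alone. Of 87 members, 55 of them with 0 IgG reads, 53 were higher, 7 lower and 27 not passed. Adjusted over the list alone the counts were 55 and 8, and miR-3529-3p (993 and 2011 RPM) did not pass. Entries that overlap tRNA, rRNA, snRNA, snoRNA or repeats held 0.0113% ± 0.0018 and 0.174% ± 0.15, a ratio of 12.3 (7.31 to 19.7), 5.90 (2.14 to 13.0) against IgG replicate 1 alone and 24.9 (13.1 to 43.4) against IgG replicate 2 alone. Without miR-1290, which had 12 of the 19 IgG reads, the ratio was 4.75 (1.89 to 9.94). Of 10 members, 6 of them with 0 IgG reads, 5 were higher, 2 lower (miR-4454 and miR-1260a) and 3 not passed. Adjusted over the list alone the counts were 6 and 2.

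**Figure D3:**
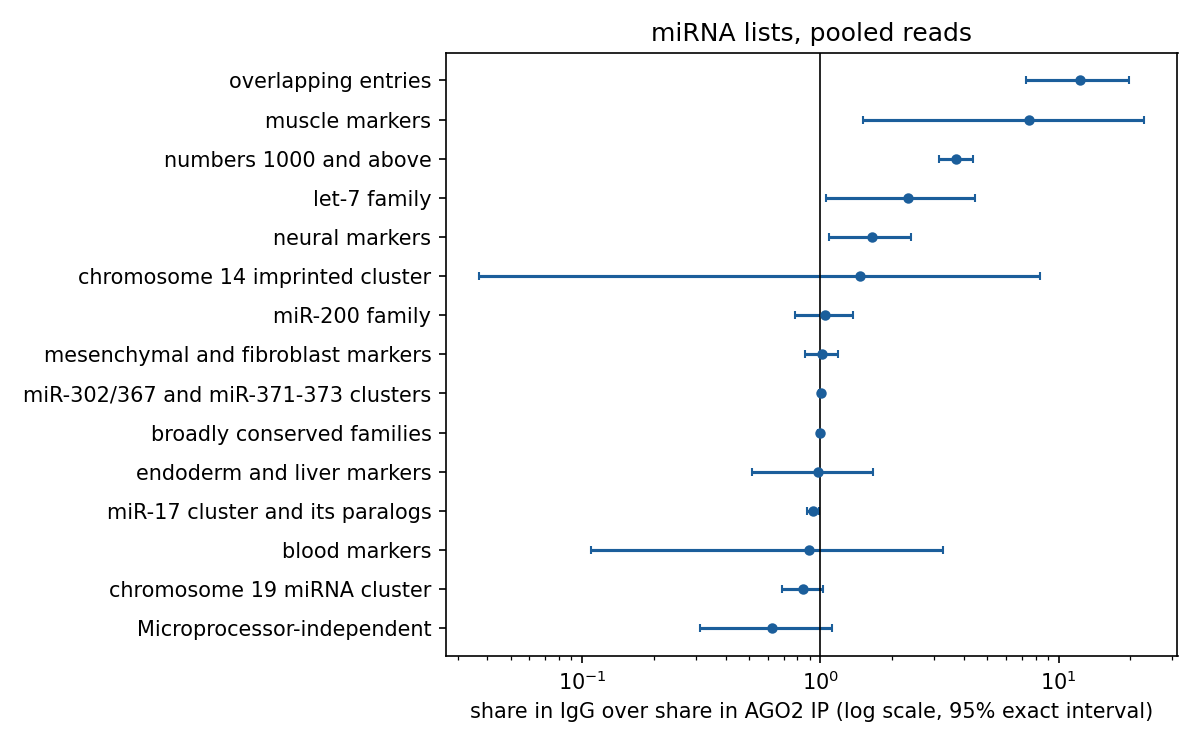
Ratio of the pooled IgG share to the pooled AGO2 share for each of the 15 miRNA lists (log horizontal axis, no unit), with exact 95% intervals that cover counting error only. The miR-302 and miR-371 clusters lie at 1.01, numbers 1000 and above at 3.72 and overlapping entries at 12.3; with all 6 other scalings the first of these lies below 1.

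camera, which sets a list against all other miRNAs, called 0 of the 15 lists on the limma values. The smallest adjusted p was 0.116, for the miR-302 and miR-371 clusters (unadjusted p = 0.0078), followed by 0.265 for neural markers (0.035), and no other list had an unadjusted p under 0.05. With an estimated correlation the smallest adjusted p was 0.902. The median and mean log2 fold changes were above 0 in all 15 lists, whereas camera gave 10 of them the lower direction, the miR-302 and miR-371, miR-17, chromosome 19, miR-200, conserved, let-7, neural, mesenchymal, overlapping and 1000-and-above lists. That direction is relative to the other tested miRNAs. Of the 496, 263 had 0 IgG reads and the median was 2.12, so it does not show lower shares with AGO2. On limma values, draws of IgG libraries from the AGO2 composition gave a median of 4 called lists (0 to 6). With members at 0 IgG reads placed at their limit of 3 reads, the median was above 0 in 1 list, the miR-17 list (0.093). That limit is a lower bound on the fold, and it lies below 0 for any such member under 220 RPM in AGO2. Medians below 0 on this scale therefore reflect the IgG depth and do not show lower shares with AGO2. camera on the edgeR fit called 5 of 11 lists: numbers 1000 and above lower with AGO2 (adjusted p = 2.9e-05), overlapping entries lower (0.037), and the miR-17 list (0.016), the conserved list (0.022) and the miR-302 and miR-371 list (0.031) higher. With IgG libraries drawn from the AGO2 composition it called a median of 2 lists (0 to 5). None of these 5 held with an estimated correlation, where each had an adjusted p = 0.297, and with scaling by total counts only the numbers 1000 and above were called (adjusted p = 0.00033). Without AGO2 replicate 1 or 2, camera on limma values gave overlapping entries and numbers 1000 and above the lower direction. The filter then kept only miRNAs with IgG reads, so rare members entered only through the group where they were high. In the full fit, 32 of the 87 members numbered 1000 and above had IgG reads. Their median log2 fold change was -0.93, against 1.83 for all 87. The direction without an AGO2 replicate is therefore no separate evidence on these lists. fry, which asks whether the members of a list move 1 way on balance, called all 15 higher, and gave a median of 15 (range 12 to 15) with IgG libraries drawn from the AGO2 composition.

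Arm usage asked whether the strand found with AGO2 differs from that in the control. The 5 hairpins with the most reads kept the same dominant 3p arm in both kinds of library. The 5p arm of miR-302b held 0.545% ± 0.017 of the hairpin's AGO2 reads and 0.426% ± 0.13 of its IgG reads (SD, n = 2), that of miR-302a 2.34% ± 0.11 and 1.84% ± 0.025, and that of miR-302c 3.01% ± 0.051 and 1.89% ± 0.36. For miR-302d it held 0.323% ± 0.0047 and 0.374% ± 0.34, and for miR-367 0.341% ± 0.026 and 0.565% ± 0.079. limma on the log2 ratio of arms did not call any of these 5 (adjusted p from 0.096 to 0.858), and all 22 hairpins tested had the same major arm in both groups. It called 7 of the 22, with 11 at an unadjusted p under 0.05: miR-200c (adjusted p = 0.00088), miR-130a (0.0023), miR-25, miR-92b and miR-205 (each 0.0027), miR-221 (0.0036) and miR-148a (0.018). All 7 had 0 minor-arm reads in IgG, where 0 reads allow a share of up to 4.62% to 7.50%, and their highest minor-arm share in AGO2 was 0.334%, so an arm difference was not detectable at this depth. Draws of IgG libraries from the AGO2 composition gave a median of 11 calls (range 4 to 16). Without AGO2 replicate 1 the count was 2, without AGO2 replicate 2 it was 0, without IgG replicate 1 it was 19 and without IgG replicate 2 it was 24.

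Detection followed depth. At least 10 reads were found for 348 and 342 miRNAs in the AGO2 libraries and for 38 and 31 in the IgG libraries. Thinned to the 4628 reads of the smallest library, the 4 libraries had 28, 28, 26 and 31. Over the 496 tested miRNAs the log2 RPM values of the AGO2 libraries had a Pearson correlation of 0.989 (Spearman 0.974) and those of the IgG libraries 0.688 (0.676), and pairs of an AGO2 and an IgG library had 0.718 to 0.801 (0.614 to 0.725). Over the 43 miRNAs with a mean of at least 1000 RPM the corresponding Pearson correlations were 0.999, 0.964 and 0.967 to 0.992. These correlations are across miRNAs, which are not independent replicates. A chi-square test of read counts gave 3.63 per degree of freedom between the AGO2 libraries and 1.69 between the IgG libraries, so neither pair held the same counts within sampling noise. It gave 1.31 between AGO2 replicate 2 and IgG replicate 1, 1.63 between AGO2 replicate 1 and IgG replicate 1, and 3.19 and 3.01 between the AGO2 libraries and IgG replicate 2. For the same difference in shares these values grow with read number, so pairs of unlike depth cannot be ranked by them.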

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

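The limma counts, 258 higher and 13 lower with AGO2, were computed under 25 other settings. Scaling by total counts is the RPM scaling itself. Added after the data were seen were edgeR with TMM factors, TMM scaling in limma, the pseudocounts, the minimum of 1000 RPM, the fit without a trend and the thinning. Both counts stayed within 1.5 times of the above with RLE (263 and 11), upper quartile (256 and 12) or TMM scaling (266 and 9), any read count above 0 (292 and 9), a 2-fold threshold (233 and 9), no overlapping entries (253 and 11), and pseudocounts of 0.1 (269 and 13), 10 (223 and 15) and 100 RPM (207 and 13). Relative to RPM, the scalings moved the median log2 fold change over all 496 miRNAs from 2.12 by 0.10 (RLE), 0.12 (upper quartile) and 0.23 (TMM). edgeR gave 0 higher and 4 lower with total counts, RLE, upper quartile and TMM factors (28, 29, 39 and 32 at an unadjusted p under 0.05), and DESeq2 1 higher and 13 lower. Raw reads gave 478 higher and 0 lower, by construction, since depth stays in the fold. At least 10 counts in each of 2 libraries left 328 miRNAs with 125 higher and 7 lower, and 50 counts summed over the libraries left 257 with 69 higher and 5 lower; fewer of the miRNAs with few reads were then tested. The 1000 RPM minimum gave 0 and 0 of 43, limma without the trend 257 and 23, and thinning a median of 8 higher (2 to 18) and 11 lower (5 to 18). Leaving out a library gave 0 to 353 higher and 2 to 96 lower. Without AGO2 replicate 1 or 2 the filter leaves 231 miRNAs, none with 0 IgG reads, and a lone library is assumed to vary like the other group. The replicate block gave 246 higher and 4 lower, 7 hairpins and 0 lists. Same-numbered libraries deviated together with a Pearson correlation of 0.387 and a Spearman correlation of -0.0065 over 58 miRNAs, and no label ties the numbers to a shared culture.

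Lists called on limma values numbered 0 with an estimated correlation, the block or 10 counts in each of 2 libraries, 15 with fry, 1 with edgeR camera on total counts, 5 with edgeR camera on TMM factors, and 0 to 2 when a library was left out. The miR-302 and miR-371 share of AGO2 reads, 81.0%, was 73.1% with miR-302b-3p left out of all counts. Detected miRNAs, 345 per AGO2 library and 34.5 per IgG library on average, came to 732.5 and 187.5 with a minimum of 1 read, 413.5 and 62.5 with 5, 200 and 9 with 50, and 28 and 28.5 after thinning. Called hairpins, 7, came to 1 with at least 50 counts per library, 164 with 10 counts over the 4 libraries, 13 with a pseudocount of 1, and 0 to 24 when a library was left out. Apart from the settings whose construction is given, the cause was not tested.

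Of the single named miRNAs' log2 fold changes, 955 values under other settings kept sign and side of the threshold, 64 passed it with the same sign, 125 no longer passed it, and 97 changed sign, 6 of these past the threshold both ways. Each scaling moves the folds of abundant miRNAs by about the same amount, so their values near 0 change sign. This does not cover miR-486-5p, miR-142-3p and miR-122-5p, with main log2 fold changes of 2.45, 2.17 and 1.89 and 1 IgG read each. They also changed sign in edgeR with total counts. Scaling by RLE gave 0.15 for miR-302b-3p, 0.15 for miR-302a-3p, 0.010 for miR-302d-3p, 0.063 for miR-19b-3p, 0.0086 for miR-520g-3p and 0.016 for miR-200c-3p. In that order of miRNAs, upper quartile scaling gave 0.18, 0.19, 0.048, 0.10, 0.046 and 0.054, and TMM scaling 0.47, 0.47, 0.33, 0.38, 0.33 and 0.33. edgeR with RLE factors gave 0.11 for miR-302b-3p, 0.11 for miR-302a-3p, 0.033 for miR-19b-3p, 0.028 for miR-520g-3p, 0.021 for miR-200c-3p, -0.24 for miR-486-5p, -0.52 for miR-142-3p and -0.33 for miR-122-5p. edgeR with upper quartile factors gave 0.29, 0.29, 0.20, 0.20, 0.19, -0.072, -0.35 and -0.17 for these 8 and 0.17 for miR-302d-3p. edgeR with TMM factors gave 0.20, 0.20, 0.11, 0.11, 0.10, -0.16, -0.44 and -0.25 for the 8 and 0.072 for miR-302d-3p. DESeq2 gave 0.14, 0.14, 0.057, 0.051, 0.043, -0.24, -0.52 and -0.35 for the 8 and 0.013 for miR-302d-3p. edgeR with total counts gave -0.36 for miR-486-5p, -0.64 for miR-142-3p, -0.081 for miR-375 and -0.45 for miR-122-5p, and the pseudocount of 100 RPM gave -0.21 for miR-122-5p.

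Raw reads gave 7.43 for miR-302b-3p, 7.44 for miR-302a-3p, 7.30 for miR-302d-3p, 7.33 for miR-19b-3p, 7.10 for miR-520g-3p, 7.23 for miR-200c-3p, 5.09 for miR-200a-3p, 6.41 for miR-128-3p, 6.01 for miR-124-3p, 5.48 for miR-125b-5p, 6.51 for miR-3529-3p, 6.12 for let-7a-5p, 2.23 for let-7d-5p, 0.95 for miR-6873-3p, 0.79 for miR-499a-5p, 0.90 for miR-1260a, 0.79 for miR-410-3p and 0.29 for miR-1290. The 6 past the threshold both ways, all under raw reads, were miR-6880-5p (0.58), miR-7977 (2.25), miR-3960 (2.00), let-7g-5p (1.90), miR-4454 (3.48) and miR-29b-3p (6.75). For the miRNAs that changed sign when a library was left out, the values with a library left out, of either sign, ranged from -0.033 to 0.011 for miR-302b-3p, -0.061 to 0.048 for miR-302a-3p, -0.051 to 0.12 for miR-302c-3p, -0.23 to 0.63 for miR-18a-5p, -0.96 to 5.85 for miR-486-5p, -1.23 to 5.57 for miR-142-3p, -0.47 to 0.71 for miR-520c-3p, -0.42 to 0.13 for miR-520g-3p, -0.27 to 0.35 for miR-375, -1.99 to 5.77 for miR-122-5p, -5.88 to 2.87 for let-7d-5p, -0.33 to 0.047 for miR-200c-3p and -0.32 to 1.30 for miR-141-3p. A single IgG read is worth 111 or 216 RPM, which limits what the IgG libraries can show of low miRNAs.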

Other observations

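Most hairpins of the AGO2 libraries had a dominant arm. Of 830 hairpin names with both arms listed, 146 had at least 100 AGO2 reads. In 53 of them the 5p arm held over 90% of the reads, in 59 the 3p arm did, and in 34 neither arm did. Between the AGO2 libraries, 19 of 75 miRNAs with at least 1000 reads differed by more than counting error, though by little: the SD of their log2 ratio was 0.11. The largest difference was in miR-182-5p, with 726 RPM in replicate 1 and 572 in replicate 2. miR-375, an endoderm-associated miRNA, had 919 and 748 RPM, and miR-18a-5p of the miR-17 cluster 7963 and 9471.

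Among the tests below, those on the IgG profile and on the entries high in IgG were chosen after the values were seen, as were the draws for lower calls, hairpins, lists and edgeR; the draw for higher calls was chosen before.

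Most miRNAs called higher with AGO2 had 0 IgG reads. Unequal depth with no change in composition is a candidate explanation. IgG libraries drawn from the AGO2 composition gave a median of 270 higher calls, against 258 observed, and medians of 6 lower calls, 11 hairpins and 4 lists, against 13, 7 and 0. The draws hold counting error only, and in them edgeR called 0 lower, against 4 observed. A biological enrichment of some of these miRNAs with AGO2 stays open, since under 1 IgG read was expected for 236 of the 258.

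The IgG libraries held the AGO2 profile, with the miR-302 and miR-371 clusters at 81.4% of reads. Unloaded duplex RNA on the beads would raise the minor arms. Their share, pooled over hairpins, was 0.867 times that in AGO2 (0.736 to 1.01), which argues against it for the pooled reads. Of the 30093 AGO2 minor-arm reads 9096 were of miR-302a, so this says little of hairpins with few reads. Precursor RNA could not be tested, since values are given per mature miRNA and the library preparation is not given. Reads of the AGO2 libraries carried over at 1 rate may account for the profile: the spread of log2 ratios beyond counting error was 0.44 over both IgG libraries (0.26 to 0.64, 81 miRNAs), 0 for IgG replicate 1 alone (0 to 0.42, 63 miRNAs) and 0.29 for IgG replicate 2 alone (0 to 0.58, 40 miRNAs), and these intervals overlap. The pooled value lies between the bounds set for and against this. It includes miR-361-5p, with 0 IgG reads where 5.17 were expected over both libraries. The spread without miR-361-5p was not computed, so how far the pooled value rests on this miRNA is open. AGO2 bound to the control beads would hold the same miRNAs, and no test was run for it. Carry-over therefore cannot be told apart from AGO2 on the beads. Read sequences or an input library, not used here, would bear on this question.

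Some entries had a higher share in IgG than in AGO2 by an exact binomial test adjusted over 879 names: 2 in IgG replicate 1 and 11 in IgG replicate 2, of which 2, miR-6873-3p (ratios 109 and 60.8) and miR-7977 (20.2 and 54.1), stood out in both. The adjusted p in IgG replicate 2, from 1.6e-21 for miR-1290 to 0.045 for let-7d-5p with 2 reads, argues against counting error for the 11 as a set; copies of single molecules, which this test takes as separate reads, were not tested. Reads carried over at 1 rate would give ratios near 1. For the 9 entries with under 5 expected IgG reads the lower bounds in IgG replicate 2 were at least 7.20. All 11 entries were picked by a test in that library, so these bounds are no separate evidence. In IgG replicate 1 the interval lay above 1 for miR-6873-3p (53.8 to 211), miR-7977 (8.47 to 41.3) and miR-6743-5p (7.23 to 374, 2 reads). This argues against carry-over at 1 rate for miR-7977 and for miR-6873-3p, whose bound was over 10 in both libraries. It stays open for the other entries, whose intervals against IgG replicate 1 held 1 or, for miR-6743-5p, rested on 2 reads. Fragments of tRNA, rRNA, snRNA, snoRNA or repeats may be a source, as the list fixed for them had 12.3 times the share in IgG. Of its 19 IgG reads 12 were of miR-1290, itself 1 of the 11 entries, and without miR-1290 the ratio was 4.75 (1.89 to 9.94). Only miR-1290 of the 11 is on the list, so for the rest this cannot be told apart from other origins. The need for at least 0.5 of the entries to be on the list was added after the values were seen. No biological explanation was tested.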
